A study of Mus musculus with 2 samples.

How the data were processed

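RNA of embryonic day 10.5 mouse midbrain was measured in 2 libraries, 1 from a pool of 69 embryos (replicate 1) and 1 from a pool of 51 embryos (replicate 2), called biological replicates in the labels. Per the labels' protocols, RNA was extracted with the mirVana kit, 10 ng of RNA larger than 200 nt was the starting amount and spike-in RNAs were added. The labels call the assay total RNA-seq, while the manual of the SMARTer Ultra Low kit, which primes on poly(A) tails, is among the protocols they link. Which transcripts were captured and whether strand was kept are therefore taken as unknown, and transcripts without a poly(A) tail and antisense pairs are read with that limit.

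Per the file headers, each library has a gene table and a transcript table on the mm10 assembly with GENCODE M4 annotation, derived from transcriptome alignments. The aligner and the quantifier are not given in the sources used here, although the column names are those RSEM writes. The deposited expected counts are estimates that share reads among transcripts and genes and need not be whole. The deposited TPM values divide those counts by effective length and scale each library to the same fixed total, spike-ins included. The deposited FPKM values are counts scaled by effective length and library total, and were used as an alternative. The deposited bounds of the TPM credible interval are a signal in TPM units, whose level the headers do not give, and show the precision of single genes. The deposited isoform percent is each transcript's share of its gene. Effective length was the length less 99 nt, so RNAs near or under 100 nt get unstable values or none.

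Names, biotypes and positions were taken from GENCODE M21 on GRCm38, the same assembly as mm10, matched on the Ensembl gene identifier without its version. Of 43346 identifiers 42462 matched. The 884 others, with 0.244% and 0.251% of the counts, stayed in the tables under their identifiers. Positions are those of M21, and gene models may differ from M4. Besides genes, the tables hold 97 spike-in rows and 26248 tRNA rows, which stayed out of library sizes and tests. The total expected count was 47128426 in replicate 1 and 52189568 in replicate 2.

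Before the data were examined, 35 gene lists, the tests, the alternatives and the rule for named genes were fixed. A list name, Drgx, had no match. In all 628 genes were in lists, 31 of them in more than 1. Detection meant at least 1 TPM in both libraries. A list's level was its median log2(mean TPM + 1), as a percentile of 10000 random lists of as many protein-coding genes. Random lists of detected protein-coding genes, the alternative, give equal or lower percentiles, since undetected genes are left out of them. Regional contrasts were differences of list medians of log2(TPM + 1) within each library.

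For differences between the libraries, expected counts were rounded and scaled by TMM factors (edgeR 4.0.16), 1.01 for replicate 1 and 0.988 for replicate 2. Each of 14768 genes with a mean of at least 1 TPM had a two-sided exact binomial test with Benjamini-Hochberg adjustment. A call needed an adjusted p below 0.05 and 2-fold, with 0.5 added to each count in ratios. With 1 library on each side no model of biological spread can be fitted, so these tests cover counting error only, and 7866 genes (53.3%) had an adjusted p below 0.05 at any size. List shifts were median log2 ratios of members with a mean of at least 1 TPM, for lists with at least 5 such members, against 10000 random lists matched on expression in 50 bins. The skeletal muscle and Hox lists had too few. PCR copies are not independent molecules, so intervals and floors of 3 counts cover counting error only.

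The procedure was tested on simulated counts for the comparison of replicate 1 with replicate 2 over 14768 genes: 96.0% of 100 genes changed 3-fold and 98.0% of 100 genes changed 6-fold were called, and 0% of 14568 unchanged genes. List shifts were checked on normal noise of the same spread for every gene, not on counts. There, 6 of 100 random lists fell outside the central 95%.

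The rule for named genes took, of each list, up to 4 members with the highest and 2 with the lowest mean TPM; the 10 highest nuclear protein-coding genes that are not ribosomal proteins and the 10 highest genes that are neither protein coding nor mitochondrial; per direction up to 10 called genes with the largest ratio and a mean of at least 5 TPM; 22 regional, progenitor, neuronal and sex-linked genes; and the isoforms of 16 genes. Other genes are marked where named. Some genes that this rule took are not reported here; list counts and medians include them. Alternatives were other TPM minimums and pseudocounts, DESeq2 1.42.0 size factors, TPM without further scaling, FPKM, posterior mean TPM, other filters and folds, and each replicate left out. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3.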

Results

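Total RNA of the midbrain was profiled by RNA sequencing in mouse embryos of the B6NCrl strain at embryonic day 10.5, when this part of the neural tube is mostly dividing neuroepithelium with a first set of neurons. The labels give 1 group and 2 biological replicates, each a pool of male and female embryos: 69 embryos for replicate 1 and 51 embryos for replicate 2. The gene tables summed to 47128426 expected counts in replicate 1 and 52189568 in replicate 2. At 1 TPM, a length-corrected share of all transcripts, or more in both libraries, 12477 of 21474 protein-coding genes were detected, and 8199 of them reached 10 TPM. With a single group no condition can be tested, so the comparisons are between gene lists within the libraries and between the libraries. Values are in TPM, as mean ± SD over the 2 libraries (n = 2) or as replicate 1 and then replicate 2.

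Which regional programmes the dissected tissue carried was addressed with lists of midbrain, isthmus, forebrain, hindbrain and Hox genes. Otx2, a homeobox gene required for forebrain and midbrain, was the highest midbrain identity gene at 130.4 TPM ± 10.8. Its relative Otx1 followed at 42.1 TPM ± 6.0, the homeobox gene Meis2 at 33.3 TPM ± 5.6 and Dmbx1, a homeobox gene of the diencephalon and midbrain, at 33.0 TPM ± 0.40. In all, 11 of 12 midbrain identity genes were detected. The list median of 24.6 TPM lay at the 96.9th percentile of 10000 random lists of protein-coding genes, and at the 63.4th of random lists of detected protein-coding genes (given second below). The engrailed genes, which pattern the midbrain and anterior hindbrain, differed in level: En1 stood at 4.60 TPM ± 0.20 and En2 at 0.815 TPM ± 0.15. Pax7, a gene of the dorsal midbrain, was low at 1.47 and 1.12 TPM.

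Genes of the isthmic organizer, the signalling centre at the border of midbrain and hindbrain, were detected for 14 of 15 members with a list median of 12.2 TPM. Cnpy1, a regulator of FGF signalling, led the list at 98.2 TPM ± 24.4. Next came Dusp6, a phosphatase induced by FGF signalling, at 48.7 TPM ± 8.0, Fgf17 at 25.8 TPM ± 5.2 and the FGF antagonist Spry2 at 23.2 TPM ± 1.8. The organizer's own signals Fgf8 and Wnt1 stood at 23.2 TPM ± 2.1 and 19.5 TPM ± 1.3. Lmx1b, a LIM homeobox gene that maintains Wnt1 expression, was at 2.46 TPM ± 0.23. Pax2, one of the early genes of this border, was at 0.50 and 0.93 TPM. Otx2 lies at chromosome 14, 48657677 to 48673819, En1 at chromosome 1, 120602418 to 120607992, En2 at chromosome 5, 28165694 to 28172166, and Pax2 at chromosome 19, 44756045 to 44837871 (GRCm38). The deposited credible intervals of En2 ran from 0.725 to 1.09 TPM and from 0.558 to 0.859 TPM. Those of Pax2 ran from 0.382 to 0.693 TPM and from 0.737 to 1.17 TPM.

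Forebrain genes were present at lower levels, with 13 of 19 detected and a list median of 5.05 TPM, at the 59.9th and 0.06th percentile. The LIM homeobox gene Lhx2 reached 22.2 TPM ± 3.3, Dlx1 14.7 TPM ± 6.1, Sp8 10.2 TPM ± 0.021 and Nkx2-1 7.85 TPM ± 0.11. Tbr1 at 0.22 and 0.20 TPM and Vax1 at 0.04 and 0.09 TPM were near the floor. Six3 stood at 6.70 and 3.41 TPM. Against detected genes, the lists of dorsoventral midbrain domains described below were also low. The basal plate list lay at the 0.87th percentile, the floor plate list at the 1.66th and the roof plate list at the 8.16th. A low percentile of this kind does not mark the absence of a region. Of the hindbrain list, 5 of 16 genes were detected and the median was 0.233 TPM, at the 5.39th percentile. A median under 1 TPM lies below every random list of detected genes by construction. Irx3, an iroquois gene that is not restricted to the hindbrain, was its highest member at 42.7 TPM ± 2.2. Gbx2, which opposes Otx2 at the border of midbrain and hindbrain, stood at 3.49 TPM ± 0.65. Otx2 exceeded Gbx2 by 38.3 ± 10.3 times.

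None of the 39 Hox genes, which mark the hindbrain behind its first segment and the spinal cord, reached 1 TPM in both libraries. Zero counts were listed for 28 of them in replicate 1 and 23 in replicate 2, where a count of 0 allows a median of up to 0.0575 and 0.0493 TPM. Hoxa2, the most anteriorly expressed Hox gene, was at 0.24 TPM in replicate 1 (11 counts) and at 1.67 TPM in replicate 2 (89 counts). Hoxb1 was at 0.10 and 0.12 TPM and Hoxb2 at 0.02 and 0.08 TPM. Hoxa3, Hoxb3 and Hoxc12 were listed at 0 TPM in both. On the log2(TPM + 1) scale the midbrain median exceeded the forebrain median by 2.08 ± 0.73, the hindbrain median by 4.26 ± 0.57 and the Hox median by 4.55 ± 0.47. The midbrain list lay above in both libraries. The lists hold different genes, and Otx2 and Dmbx1 are not restricted to the midbrain. The contrasts therefore do not measure how much forebrain or hindbrain tissue was present. The Hox median was 0 in both libraries, so the Hox difference is the midbrain median itself. Its SD is that of the midbrain list. The sizes of the differences rest on the 1 added to each TPM. With 0.1 added, the hindbrain and Hox differences were 6.19 and 7.82. Among genes of at least 0.5 TPM the hindbrain difference was 2.46.

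**Figure D1:**
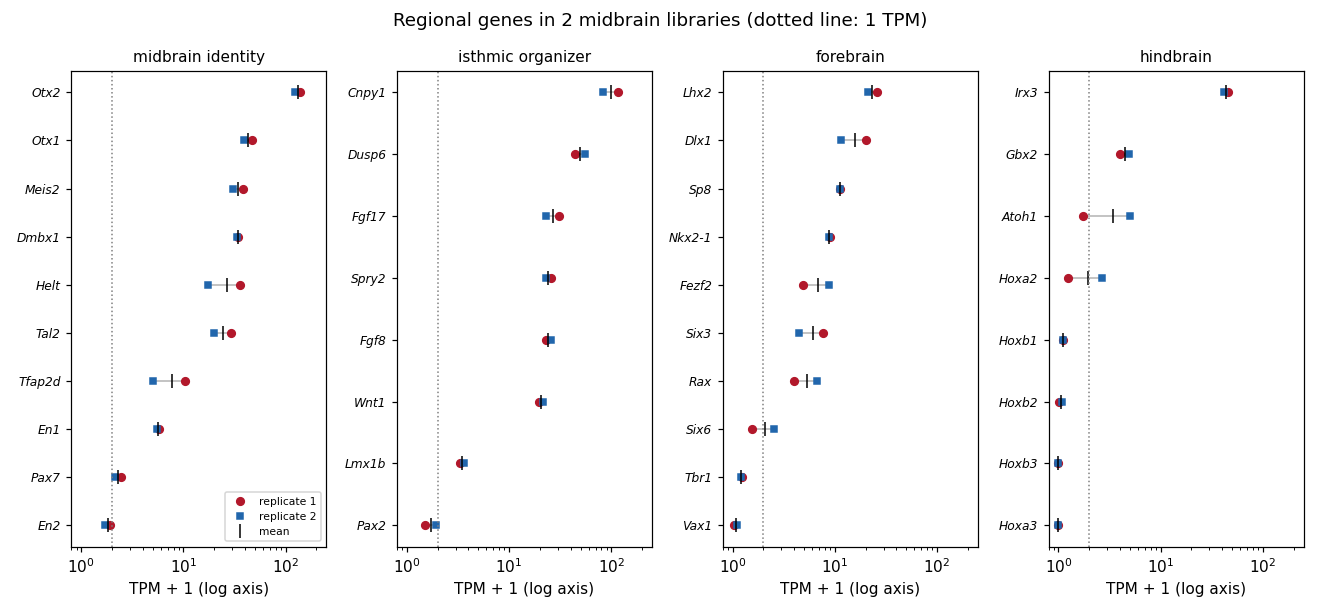
TPM + 1 on a log axis of the genes named in the text from the midbrain identity, isthmic organizer, forebrain and hindbrain lists in replicate 1 (circles) and replicate 2 (squares), with the mean as a bar and 1 TPM as a dotted line. Otx2 stands at 130.4 TPM and most Hox genes shown lie at or near 0.

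Lists of the dorsoventral domains described which parts of the midbrain wall and which neurons were sampled. In the floor plate and dopaminergic lineage, 14 of 16 genes were detected with a median of 7.63 TPM. Msx1, which is shared with the roof plate, was the highest at 129 TPM ± 3.6, followed by the guidance cue Ntn1 at 22.4 TPM ± 0.98, the dopaminergic determinant Lmx1a at 14.3 TPM ± 2.1 and Ddc, which makes dopamine from L-DOPA, at 12.5 TPM ± 1.3. The floor plate genes Foxa2 and Shh were at 9.55 TPM ± 1.0 and 6.46 TPM ± 0.085. Nr4a2 and Th, genes of postmitotic dopaminergic neurons, were at 11.7 and 5.89 TPM and at 11.9 and 6.68 TPM. The later dopaminergic genes Pitx3 (0.14 and 0.36 TPM) and Slc6a3, the dopamine transporter (0.09 and 0.08 TPM), were not detected.

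Of the basal plate and motor nucleus genes, 8 of 12 were detected with a median of 5.96 TPM. Nkx6-2 stood at 62.0 TPM ± 15.8, Nkx2-9 at 22.5 TPM ± 2.2, Pou4f1 at 20.9 TPM ± 0.17 and Isl1, a LIM homeobox gene of motor neurons, at 15.8 TPM ± 2.5. Chat, which makes acetylcholine, was at 0.06 and 0.03 TPM and Mnx1 at 0 TPM. Roof plate and dorsal midline genes were detected for 16 of 18 members with a median of 11.1 TPM: after Msx1 came Zic4 at 24.8 TPM ± 4.9, Wnt1 and Msx2 at 17.6 TPM ± 2.8. Ttr, a gene of the choroid plexus, and Gdf7 were the lowest members at 0.40 and 2.98 TPM and at 0.16 and 0.41 TPM.

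GABAergic lineage genes were detected for 9 of 10 members (median 11.2 TPM, 15.85 in replicate 1 and 6.13 in replicate 2) and glutamatergic lineage genes for 12 of 13 (median 13.7 TPM, 17.7 and 9.63). The GABAergic selectors Helt, Tal2 and Gata3 were at 25.7 TPM ± 12.9, 23.6 TPM ± 6.8 and 16.4 TPM ± 10.6. The vesicular GABA transporter gene Slc32a1 was not detected, at 0.58 and 0.21 TPM. Among the glutamatergic genes, Ebf1 was at 34.2 TPM ± 10.3, Neurog2 at 31.3 TPM ± 12.4, Neurog1 at 29.3 TPM ± 0.33 and Lhx5 at 23.5 TPM ± 4.2. Ebf3 was at 2.46 and 1.66 TPM, and Pou4f2, a gene of later projection neurons, at 0.19 and 0.16 TPM.

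Where the tissue stood between proliferation and differentiation was described with lists of progenitors, cell cycle, neurons and glia. All 20 neuroepithelial progenitor genes were detected (median 32.6 TPM, 99.8th and 88.3rd percentile), led by the intermediate filament gene Vim at 1002 TPM ± 63.1, the Notch target Hes5 at 642 TPM ± 79.9, Fabp7 at 509.8 TPM ± 159 and Msi1 at 178 TPM ± 24.0. Nes and Sox2, markers of neural progenitors, were at 119 TPM ± 19.5 and 22.1 TPM ± 2.0. Sox3 and Sox1 were the lowest at 4.45 TPM ± 0.33 and 2.80 TPM ± 0.13. All 25 cell cycle genes were detected with a median of 231 TPM, above every one of the random lists of either kind. Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, reached 655 TPM ± 51.4, Cdk1 408 TPM ± 53.8, Ccnb1 395 TPM ± 18.7 and Cdc20 353 TPM ± 14.1. Ccne1 and Mki67 were the lowest at 70.1 TPM ± 14.1 and 37.6 TPM ± 2.3.

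Neuronal genes were also present: 19 of 20 proneural and newborn neuron genes were detected with a median of 32.5 TPM, at the 99.8th and 88.0th percentile. The neuronal tubulin gene Tubb3 stood at 463 TPM ± 140.4, the proneural target Hes6 at 229.7 TPM ± 68.7, the growth cone gene Gap43 at 141 TPM ± 42.3 and Stmn2 at 138 TPM ± 52.9. Insm1 (4.01 and 2.53 TPM) and Atoh1 (0.75 and 4.07 TPM) were the lowest. Mature synapse genes were lower, with 9 of 12 detected and a median of 4.26 TPM (5.925 and 2.99 TPM by library, 55.1st and 0.16th percentile). Dlg4 was at 16.4 TPM ± 4.8, Snap25 at 14.3 TPM ± 5.2, Syp at 14.3 TPM ± 5.7 and Rbfox3 at 6.73 TPM ± 0.38. Slc17a7 (0.19 and 0.39 TPM) and Nefh (0.24 and 0.20 TPM) were not detected. Of the glial genes 8 of 14 were detected (median 4.64 TPM). The glutamate transporter gene Slc1a3, also used by radial glia, was at 22.7 TPM ± 3.9. Pdgfra, also a member of the head mesenchyme and neural crest list, was at 13.4 TPM ± 2.4 and Mbp at 11.3 TPM ± 1.2. Gfap and S100b, genes of mature astrocytes, were at 0.04 and 0.07 TPM and at 0.02 and 0.04 TPM.

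All 16 neural RNA-binding protein genes were detected with a median of 13.7 TPM (18.6 and 9.04 TPM by library). Ptbp1, the splicing repressor of non-neuronal cells and progenitors, was the highest at 268 TPM ± 24.4. Its neuronal relative Ptbp2 stood at 145 TPM ± 18.1 and the neuronal gene Elavl4 at 132 TPM ± 30.3. Khdrbs2 and Rbfox1 were the lowest at 4.89 TPM ± 1.2 and 2.90 TPM ± 1.7. Of the cell cycle inhibitors 5 of 7 were detected (median 15.4 TPM), led by Cdkn1c at 238 TPM ± 45.8, Cdkn2d at 52.0 TPM ± 6.5, Cdkn1a at 21.9 TPM ± 3.9 and Cdkn1b at 15.4 TPM ± 3.2. Cdkn2a was listed at 0 TPM and Cdkn2b at 0.16 and 0.07 TPM.

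Signalling targets were detected for 21 of 24 members (median 7.96 TPM). The BMP-induced genes Id3, Id2 and Id1 were at 603 TPM ± 112, 258 TPM ± 16.0 and 66.3 TPM ± 9.9. The Notch target Nrarp was at 58.6 TPM ± 4.7. Aldh1a2, which makes retinoic acid, and Cyp26c1, which degrades it, were not detected, at 0.49 and 0.69 TPM and at 0.04 and 0.76 TPM. Of the same family as Aldh1a2, Aldh1a3 was at 0.80 and 7.83 TPM and Aldh1a1 at 1.24 and 5.59 TPM. Both were chosen after their values were seen. All 20 imprinted genes were detected with a median of 69.0 TPM, above every random list of protein-coding genes and at the 99.9th percentile against detected genes. Mest stood at 1442 TPM ± 362, Grb10 at 377 TPM ± 3.6 and Ndn at 269.8 TPM ± 66.1. The antisense RNA Kcnq1ot1 and Zrsr1 were the lowest at 2.78 TPM ± 0.17 and 1.57 TPM ± 0.18. All 10 sex-linked genes were detected (median 16.6 TPM), led by Ddx3x at 129 TPM ± 4.1, Eif2s3x at 93.8 TPM ± 1.5, Kdm5c at 59.2 TPM ± 6.0 and the Y-linked Eif2s3y at 23.5 TPM ± 0.96. Xist, made in female cells, was at 15.6 and 13.2 TPM and the Y-linked Ddx3y at 11.7 and 12.5 TPM, in pools labelled as both sexes. The lowest members were Kdm5d at 10.1 TPM ± 1.9 and Tsix at 3.58 TPM ± 0.27. Tsix overlaps Xist on the other strand and cannot be separated from it where strand was not used.

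Markers of other cell types showed what else the tissue held. Haemoglobin genes were among the highest transcripts: Hbb-y stood at 6605 TPM ± 436, Hba-a2 at 3457 TPM ± 55.9, Hbb-bh1 at 3091 TPM ± 758 and Hba-x at 2534 TPM ± 163. All 10 erythroid genes were detected, with Slc4a1 at 28.7 TPM ± 0.18. Hba-a2 and its near-identical copy Hba-a1 share reads, so their separate levels are uncertain. Endothelial genes were detected for all 12 members at a median of 14.6 TPM. Their highest values were those of Egfl7 at 65.5 TPM ± 10.6, Esam at 25.4 TPM ± 1.9, Cldn5 at 25.2 TPM ± 0.33 and Kdr, a VEGF receptor, at 23.4 TPM ± 1.7. The lowest were Sox17 at 7.30 TPM ± 0.39 and Robo4 at 4.43 TPM ± 0.19. All 10 macrophage and microglia genes were detected at a median of 6.05 TPM. They were led by C1qb at 22.4 TPM ± 7.0, Tyrobp at 14.9 TPM ± 2.4, Fcer1g at 14.3 TPM ± 5.0 and Csf1r at 7.18 TPM ± 2.0. Mrc1 was at 2.75 TPM ± 0.71 and Ptprc at 1.21 TPM ± 0.12.

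Head mesenchyme and neural crest genes were detected for 16 of 17 members (median 8.45 TPM). The collagen genes Col3a1, Col1a1 and Col1a2 stood at 367 TPM ± 70.4, 111 TPM ± 54.3 and 95.6 TPM ± 32.7 and Lum at 80.5 TPM ± 15.9. Tfap2a was at 1.56 TPM ± 0.057 and Sox10, a neural crest gene, at 0.46 and 2.15 TPM. Surface ectoderm genes were detected for 8 of 10 (median 4.66 TPM). Krt8 was at 18.6 TPM ± 2.3, Krt18 at 14.1 TPM ± 6.0, Wnt6 at 8.37 TPM ± 1.4 and Cdh1 at 7.15 TPM ± 0.30. The keratin genes of later epidermis, Krt14 (0.87 and 1.00 TPM) and Krt5 (0.10 and 0.19 TPM), were not detected. Of the cranial ganglion genes 7 of 10 matched members were detected (median 2.80 TPM). Eya2 was at 10.1 TPM ± 2.9 and Ntrk2 at 7.26 TPM ± 2.6. Tlx2 and Pou4f3 were at 0.07 and 0.67 TPM and at 0.08 and 0.20 TPM. Few skeletal muscle and eye genes were detected, 3 of 8 and 3 of 9, at medians of 1.02 and 1.05 TPM. In replicate 2 alone 6 eye genes reached 1 TPM, and the eye median was 0.65 TPM in replicate 1 and 1.38 TPM in replicate 2. Tnnt1 was at 4.54 TPM ± 0.78, Actc1 at 2.81 TPM ± 0.30, Myf5 at 2.59 TPM ± 0.28 and Des at 0.97 and 2.37 TPM. Myog and Myod1 were below 0.1 TPM. The eye genes Pmel and Rax were at 3.27 and 5.70 TPM and at 2.99 and 5.73 TPM, and Dct at 1.55 TPM ± 0.24. The lens crystallin genes Cryaa (0.03 and 0 TPM) and Crybb2 (0 TPM in both) were the lowest.

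Stress and metabolic lists described the state of the dissected tissue. Immediate early and heat shock genes were detected for 8 of 11 members at a median of 4.36 TPM. Dnajb1 was at 89.7 TPM ± 10.4, Ier2 at 60.1 TPM ± 9.0, Jun at 59.3 TPM ± 1.00 and Dusp1 at 21.4 TPM ± 4.2. The inducible genes Hspa1b (0.05 and 0.16 TPM) and Fosb (0 and 0.02 TPM) were near the floor. Hypoxia and glycolysis genes were detected for 11 of 12 members at a median of 21.7 TPM, at the 95.5th and 53.0th percentile. Lactate dehydrogenase gene Ldha stood at 2638 TPM ± 673, the glycolytic gene Pgk1 at 424 TPM ± 75.1, the glucose transporter gene Slc2a1 at 218 TPM ± 40.3 and Bnip3 at 99.1 TPM ± 20.2. The hypoxia targets Vegfa and Car9 were at 1.90 TPM ± 0.092 and 0.570 TPM ± 0.014.

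Ribosomal protein genes were detected for 89 of 92 list members with a median of 574.7 TPM, led by Rpl41 at 2604 TPM ± 247, Rps19 at 1769 TPM ± 167 and Rpl32 at 1451 TPM ± 191. Rpl3l and Rpl10l were at or near 0 TPM. The name pattern behind this list also took 10 S6 kinase genes and Rps19bp1, which are not ribosomal proteins. Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, were detected for 52 of 67 members at a median of 6.16 TPM. All 8 polyadenylated histone variants were detected at a median of 647 TPM. Hist1h2ap was the exception among the former at 5492 TPM ± 567. It was followed by Hist1h4d at 292 TPM ± 15.5, Hist1h2ae at 175 TPM ± 22.4 and Hist1h3i at 96.4 TPM ± 7.1. Hist1h2ba and Hist1h4m were at 0 TPM. Histone genes of the same cluster are nearly identical in sequence, so the level of any single one is uncertain. The variants were led by H2afz at 2893 TPM ± 259, H3f3a at 2251 TPM ± 81.7, H3f3b at 1350.0 TPM ± 102 and H2afv at 839.5 TPM ± 39.6. The lowest were H1f0 at 349.8 TPM ± 40.1 and H1fx at 18.0 TPM ± 1.1. Of 8 small noncoding RNAs without a poly(A) tail 4 were detected. The signal recognition particle RNA genes Rn7s1 and Rn7s2, near-identical copies that cannot be told apart, were both at 3655 TPM. Rn7sk was at 88.7 TPM ± 4.6 and Rpph1 at 32.4 TPM ± 0.49. Terc was at 0.95 and 0.83 TPM and Rny3 at 0.

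Mitochondrially encoded genes took 0.909% ± 0.013 of the counts, spike-ins 3.33% ± 0.076, ribosomal proteins 2.08% ± 0.28, erythroid genes 0.618% ± 0.058 and replication-dependent histones 0.170% ± 0.018. As shares of TPM, which weights short transcripts more, these were 1.95%, 7.64%, 5.48%, 1.79% and 0.673%. Exact Clopper-Pearson 95% intervals of the mitochondrial share were 0.916 to 0.921% in replicate 1 and 0.897 to 0.902% in replicate 2. They cover counting error only, as do all intervals and floors here. Reads that the quantification gave to pseudogenes on other chromosomes are not part of the mitochondrial share. The mitochondrial ATPase gene mt-Atp6 was at 5131 TPM ± 9.1, mt-Atp8 at 3762 TPM ± 34.5, mt-Nd1 at 2012 TPM ± 64.7 and mt-Cytb at 1866 TPM ± 179. The list median of 0 comes from 22 mitochondrial tRNA genes, mt-Tt and mt-Tp among them, that have an effective length of 0 and cannot receive a value. The 15 measurable mitochondrial genes, 13 coding and 2 ribosomal, had a median of 753.8 TPM. Of 96 ERCC spike-ins (the other spike-in row is phiX174), 84 were above 0 TPM in both libraries, spanning 0.03 to 26626 TPM. Their Spearman rho between the libraries was 0.987, across spike-ins.

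The most abundant nuclear protein-coding genes outside the ribosome were, after Hbb-y, the cytoskeletal gene Actb at 5496 TPM ± 237, Hist1h2ap and the tubulin gene Tuba1a at 5192 TPM ± 1339. They were followed by Ppia at 5026 TPM ± 526, the ferritin gene Ftl1 at 5025 TPM ± 249, Hba-a2, Tmsb4x at 3245 TPM ± 255, Hmgn2 at 3127 TPM ± 81.8 and the translation factor gene Eef1a1 at 3119 TPM ± 195. Several of the top genes that are not protein coding overlap or copy other genes and are uncertain. Gm22133, annotated as a microRNA at 5116 TPM ± 192, lies inside Ftl1 on chromosome 7. Gm10123, at 4292 TPM ± 406, is a processed pseudogene. Gm28437, Gm29216 and Gm28661, at 4868, 1837 and 1746 TPM, are unprocessed pseudogenes that start at 24613189, 24615706 and 24614885 on chromosome 1. The nuclear RNA Malat1 was at 3200.1 TPM ± 531. Gm26917 and Gm42418, annotated as long noncoding RNAs and neighbours on chromosome 17, were at 1894 TPM ± 214 and 1592 TPM ± 85.1. Which RNA their reads stem from was not tested.

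**Figure D2:**
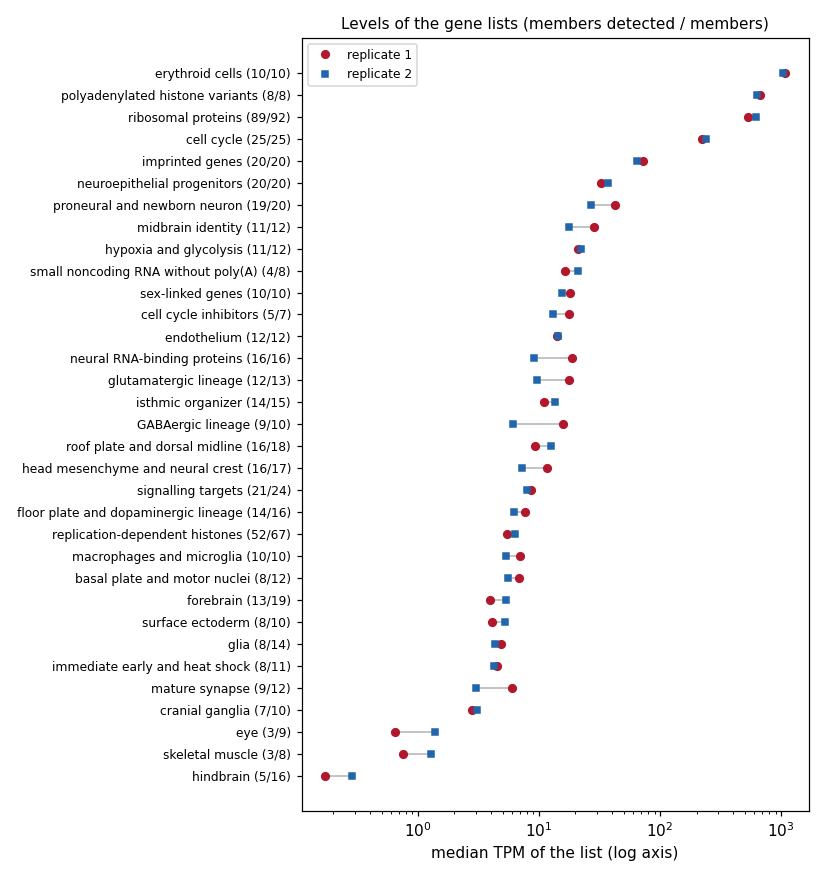
Median TPM on a log axis of each gene list in replicate 1 (circles) and replicate 2 (squares), with members detected and members listed in brackets; the Hox and mitochondrial lists, with medians of 0, are left out. Erythroid genes, polyadenylated histone variants and ribosomal proteins lie highest, and hindbrain, skeletal muscle and eye genes lowest.

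How closely the replicates matched was measured across genes, which are not independent replicates. Over 14768 genes with a mean of at least 1 TPM, log2(TPM + 1) gave a Pearson r of 0.987 and a Spearman rho of 0.987, and the median gene differed 1.12-fold. Otx2, En1, Sox2 and Mki67 were 1.06-fold, 1.00-fold, 1.07-fold and 1.03-fold higher in replicate 1, and Shh was 1.08-fold higher in replicate 2. Larger ratios were seen for Six3, Nr4a2 and Th, at 1.94-fold, 1.71-fold and 1.69-fold higher in replicate 1, none of which reached 2-fold. The libraries were not 1 library deposited a second time, since a chi-square test over 19294 genes gave 30.2 per degree of freedom.

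Which genes differed between the pools was asked next. Among called protein-coding genes with a mean of at least 5 TPM, the largest ratios towards replicate 1 were those of Penk, the enkephalin precursor, 5.15-fold (24.0 against 4.39 TPM), and the synaptotagmin gene Syt4, 4.24-fold (20.3 against 4.51 TPM). Tmem130 was 4.15-fold higher, Sybu, which tethers axonal cargo to kinesin, 3.83-fold and the neurexin gene Nrxn3 3.41-fold (15.1 against 4.41 TPM). Lhx1os, a noncoding RNA beside Lhx1, was 3.71-fold higher at 42.2 against 10.5 TPM. Higher in replicate 2 were Msx3, a homeobox gene of the dorsal neural tube, 3.49-fold (14.1 against 4.30 TPM), and Wfikkn1, a binding protein of TGF-beta family ligands, 3.47-fold (17.1 against 5.30 TPM). The tight junction gene Cldn6 was 3.06-fold higher there (8.15 against 2.81 TPM) and the forkhead gene Foxe3 2.35-fold (12.5 against 5.63 TPM).

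In this comparison 347 of 14768 genes differed at least 2-fold with an adjusted p below 0.05, 247 higher in replicate 1 and 100 higher in replicate 2. Of these, 201 and 67 were protein coding. The count was 1022 at a summed count of at least 10 in place of the TPM filter, 45 at a mean of at least 10 TPM and 1123 at 1.5-fold. The exact binomial test with Benjamini-Hochberg adjustment compares these libraries and not conditions, since each side is 1 library, and 20 simulations with counting noise alone called 0 genes. The remaining named genes are short, repeated or overlapping and are uncertain. Mir719 (chromosome 14, 60228806 to 60228915) and Gm27611 (chromosome 3, 34653178 to 34653285) had 7.51 and 5 counts in replicate 1 and 0 in replicate 2, at least 2.71-fold and 1.80-fold higher against a floor of 3 counts. Gm27582 was 3.41-fold and the pseudogene Gm10357 5.85-fold higher in replicate 1. Hist1h2aj, a member of the histone list annotated in M21 as an unprocessed pseudogene, and the histone gene Hist2h2ac were 5.20-fold and 2.52-fold higher in replicate 2. The pseudogenes Gm20430, Gm10193 and Gm6055 were 3.64-fold, 3.18-fold and 2.44-fold higher there, and the antisense RNA Gm20463 2.38-fold.

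**Figure D3:**
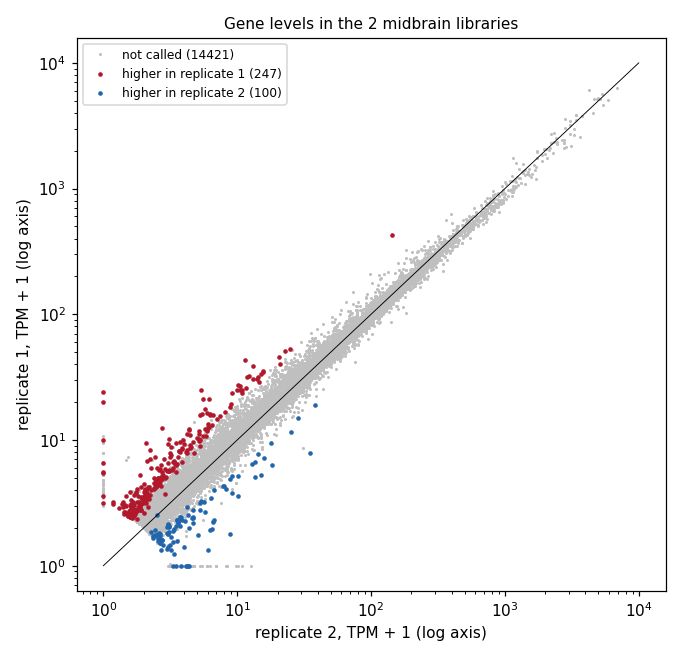
TPM + 1 in replicate 1 (vertical) against replicate 2 (horizontal), both on log axes, for 14768 genes with a mean of at least 1 TPM; red points are 247 genes called higher in replicate 1, blue points 100 genes called higher in replicate 2 and the line is equality. Most of the coloured points lie at low TPM.

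Whether gene lists moved together between the libraries was described by the median log2 ratio of each list, set against 10000 random lists of the same size matched on expression. GABAergic lineage genes were higher in replicate 1 for 9 of 9 tested members, with a median of 1.99-fold. Gata3 was 2.47-fold higher there. The other called members, Gad1 and Gad2, which make GABA, and the transcription factor gene Sox14 (all 3 chosen after their values were seen), were 3.61-fold, 3.18-fold and 8.47-fold higher. Glutamatergic lineage genes were higher for 11 of 12 members (median 1.40-fold), with Lhx1 3.35-fold and the glutamate transporter gene Slc17a6 2.31-fold higher as the called members, both chosen after their values were seen. Proneural and newborn neuron genes were higher in replicate 1 for 18 of 20 members (median 1.46-fold), including Tubb3 at 1.46-fold. Dcx, chosen after its value was seen, was called at 2.12-fold. Atoh1, the proneural gene of the rhombic lip, was called in the other direction, 5.66-fold higher in replicate 2.

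Mature synapse genes were higher in replicate 1 for 9 of 10 members (median 1.57-fold), with the AMPA receptor gene Gria2, chosen after its value was seen, called at 2.95-fold. Neural RNA-binding protein genes were higher for 14 of 16 (median 1.34-fold), with Rbfox1 called at 2.41-fold and Celf4, chosen after its value was seen, at 2.28-fold. Macrophage and microglia genes were higher for 9 of 10 members (median 1.39-fold, none called). Midbrain identity genes were higher for 9 of 11 (median 1.18-fold, Tfap2d called at 2.12-fold and chosen after its value was seen). Among members of no other list the midbrain median, 0.15 on the log2 scale, lay inside the random range. Smaller shifts towards replicate 1, close to the edge of the random range, were those of progenitor genes (13 of 20 higher, 1.04-fold) and imprinted genes (13 of 20, 1.04-fold). Both fell inside the range among members of no other list, the imprinted list also with TPM as deposited or no filter, and the progenitor list, with a median of -0.03, also after correction for GC content and length. Mitochondrially encoded genes were level with a median of -0.01 on the log2 scale, which was above random lists of that abundance. After correction for GC content and length their median was 0.10. Among them mt-Nd4l, chosen after its value was seen, was called at 2.19-fold, at only 30.7 against 13.2 TPM.

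Higher in replicate 2 were eye genes (4 of 5 tested members, median 1.93-fold), with Rax called at 2.02-fold and Six6, chosen after its value was seen, at 2.92-fold. Both are also members of the forebrain list. Without them too few eye genes remained to check this shift towards replicate 2. Hypoxia and glycolysis genes were higher there for 10 of 11 members (median 1.36-fold), surface ectoderm genes for 6 of 8 (1.30-fold), cell cycle genes for 21 of 25 (1.18-fold) and immediate early and heat shock genes for 6 of 8 (1.18-fold), none of them called. Ribosomal protein genes were higher in replicate 2 for 82 of 89 members (median 1.23-fold), and without the kinases and Rps19bp1 for 78 of 78 (1.24-fold). Replication-dependent histones were higher there for 42 of 54 (1.16-fold), with 5 called: the annotated pseudogene Hist1h2aj, Hist2h2ac and, chosen after their values were seen, Hist1h2bl, Hist1h4k and Hist1h2bn. Roof plate genes were higher for 12 of 17 (1.14-fold), with Ttr called at 7.72-fold and Rspo3, chosen after its value was seen, at 2.11-fold. Isthmic organizer genes were higher for 8 of 14 (1.15-fold), and among members of no other list their median of -0.07 lay inside the random range.

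In all, 19 of 33 lists lay outside the central 95% of random lists, 10 above and 9 below, where 1.65 would do so by chance if genes of a list varied independently, which co-regulated genes do not. The remaining 14 lay inside it, although cell cycle inhibitors fell outside under 3 alternatives, hindbrain genes under 2 and cranial ganglia under 1. Their median log2 ratios were -0.06 for forebrain, -0.25 for hindbrain, -0.02 for floor plate and dopaminergic lineage and 0.10 for basal plate and motor nuclei. They were 0.13 for glia, 0.22 for cell cycle inhibitors, -0.03 for signalling targets and 0.03 for sex-linked genes. Of the other cell types, erythroid cells had -0.17, endothelium -0.05, head mesenchyme and neural crest -0.02 and cranial ganglia -0.16. Mesenchyme and neural crest members went opposite ways. Of 17, 7 were higher in replicate 1, among them Col1a1 (1.95-fold) and Col1a2 (1.56-fold), and 10 in replicate 2. The median was -0.04 for both polyadenylated histone variants and small noncoding RNAs. Called members of these lists, all chosen after their values were seen except Rax, Atoh1 and Sox10, were higher in replicate 2 for Fezf2 (2.09-fold), Rax, Six6, Atoh1, Aldh1a1 (4.75-fold), Phox2a (2.71-fold), Sox10 (4.94-fold) and Aldh1a3 (13.1-fold), and higher in replicate 1 for Dcn (2.15-fold).

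**Figure D4:**
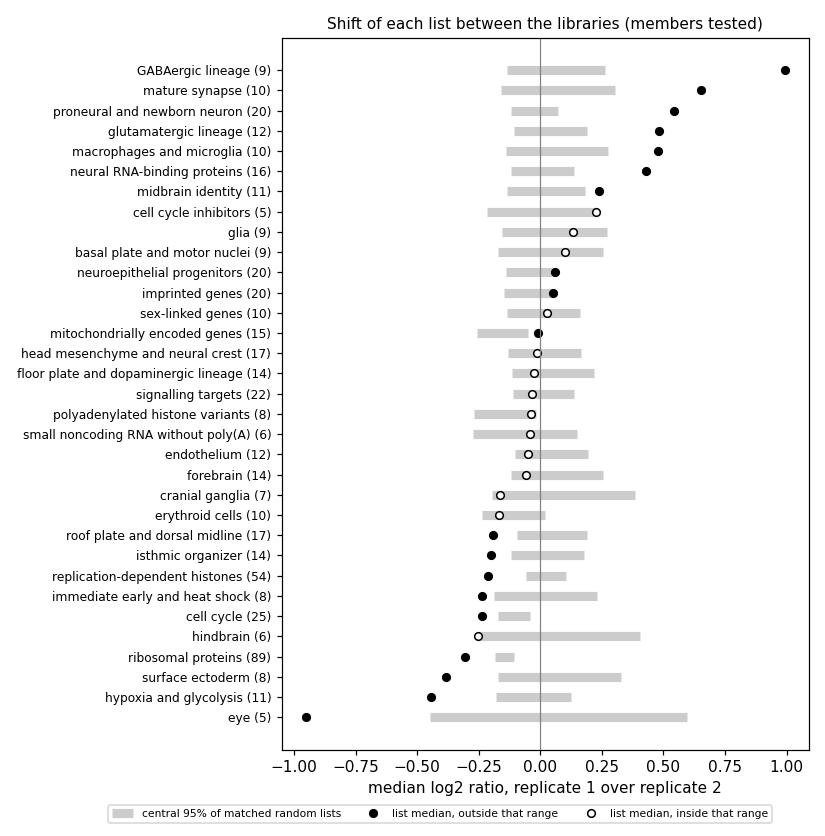
Median log2 ratio of replicate 1 over replicate 2 for each of 33 lists, with the number of tested members in brackets, and grey bars for the central 95% of random lists matched on size and expression. GABAergic, synapse, newborn neuron and glutamatergic lists lie to the right of their bars, and eye, hypoxia and ribosomal protein lists to the left.

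The transcript tables showed which isoforms carried these genes. Otx2 was mainly ENSMUST00000118578.3, with 57.0% ± 0.0071 of its transcripts, followed by ENSMUST00000119070.3 with 27.0% ± 0.47. Pkm, the pyruvate kinase gene, was mainly ENSMUST00000034834.11 with 95.7% ± 2.0, Ncam1 mainly ENSMUST00000193547.1 with 79.9% ± 2.1 and Lmx1b mainly ENSMUST00000041730.6 with 95.7% ± 3.5. Fgf8 was split among ENSMUST00000026241.7 with 25.5% ± 0.30, ENSMUST00000111928.3 with 24.5% ± 6.3 and ENSMUST00000026240.9 with 21.2% ± 5.3. The first led in replicate 1 (25.3% against 20.0% for the second) and the second in replicate 2 (28.99% against 25.75% for the first). Pax6, of 26 annotated transcripts, had ENSMUST00000090397.8 at 24.2% ± 1.5, and Ptbp1 had ENSMUST00000165704.3 at 37.2% ± 2.1. Dcx was split between ENSMUST00000033642.5 with 40.7% ± 1.1 and ENSMUST00000112851.3 with 37.9% ± 1.1, Mapt had ENSMUST00000106993.5 at 43.2% ± 1.1 and Numb had ENSMUST00000117217.3 at 34.4% ± 3.8. The leading transcript of Pax2 also differed between libraries, ENSMUST00000174490.4 with 61.4% in replicate 1 and ENSMUST00000004340.6 with 40.1% in replicate 2, at 53 and 89 counts for the gene. En1, En2, Sox2, Ptbp2 and Tubb3 have 1 annotated transcript each.

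Across 7635 genes with several transcripts and at least 5 TPM in both libraries, 7173 had the same leading transcript in both, 93.9% (exact Clopper-Pearson 95% interval 93.4 to 94.5%). Shares of transcripts that differ in few exons are estimates from shared reads.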

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

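The tRNA rows of the tables, which no comparison used, summed to 40.4 expected counts in replicate 1 and 40.0 in replicate 2. Of 26248 rows, 9 were above 0 in replicate 1, 7 in replicate 2 and 5 in both. Their median length was 73 nt and 99.8% of them had an effective length of 0, which leaves them no value, so these sums say nothing of tRNA abundance. No biological explanation was tested.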

How the results depend on the processing

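Corrections for GC content and length, lists cut to members of no other list, and the whole progenitor list set against early genes, were chosen after the data were seen. Of the alternative values computed for the main results, 157 stayed on the same side or within the replicate spread, 30 moved, 6 weakened and 3 turned. Part of the 157 could not come out otherwise. With 2 libraries, leaving 1 out always stays within the SD of a regional contrast or count share. DESeq2 size factors shift all genes and random lists almost alike, so list percentiles hold. Detected protein-coding genes and midbrain and isthmic members did not move beyond 1.5 times under any setting. Against detected genes the percentile fell from 96.9 to 63.4 for midbrain, 85.0 to 14.0 for isthmic and 99.8 to 88.3 for progenitor genes. Without replicate 1, 6 eye genes were detected in place of 3. With a minimum of 5 TPM, 7 forebrain and 1 hindbrain members passed, and Hox members ranged from 0 to 1 without one replicate. The midbrain minus hindbrain contrast was 6.19 with a pseudocount of 0.1, 2.46 for members of at least 0.5 TPM and 2.92 for means; the Hox contrast was 7.82, 3.69 and 3.92, and 3.93 with FPKM. The replicate correlation was 0.971 with a pseudocount of 0.1, 0.995 with no filter, 0.988 at 10 TPM, 0.992 with posterior means and 0.969 for transcripts. Called genes numbered 1022 (688 higher in replicate 1, 334 in replicate 2) at a summed count of 10, 45 (37 and 8) at a mean of 10 TPM and 1123 (826 and 297) at 1.5-fold, where fewer or more genes can pass by construction. Of the shifted lists, the imprinted list fell inside the random range with TPM as deposited (0.13) and no filter (0.0517), and the progenitor list (-0.0280) after correction for GC content and length, where the mitochondrial median turned to 0.10. With TPM as deposited the median of all tested genes rose to 0.0703 and the mitochondrial median with it to 0.0729, its percentile unchanged at 99.55. Among members of no other list, midbrain (0.15), isthmic (-0.0690), progenitor (0.0608) and imprinted (0.0450) shifts fell inside the range. The cause was not tested. The eye list kept too few members of no other list to be checked in this way. Of lists inside the range, cell cycle inhibitors fell outside with TPM as deposited (0.37), no filter (0.27) and the GC and length correction (0.27), hindbrain with TPM as deposited (-0.20) and no filter (-0.41), and cranial ganglia with no filter (-0.27). As shares of TPM, erythroid genes took 1.79%, mitochondrial genes 1.95%, ribosomal proteins 5.48%, replication-dependent histones 0.673% and spike-ins 7.64%, since TPM weights short transcripts more. Spike-in rho was 0.997 at 10 counts. The leading transcript was shared by 91.9% of genes at 1 TPM and 97.9% where it held 50%. Depth limits the Hox genes, where a count of 0 allows a median of up to 0.0575 TPM.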

Other observations

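Most tests below were fixed before their results were seen. The values of the progenitor list, Lin28a, Lin28b and Hmga2 included, had been seen by then, and the test on cranial ganglia was chosen after its result. Adult-type beta globin (Hbb-bt and Hbb-bs, near-identical copies summed) made up 2.94% ± 1.4 of beta-like globin TPM, 3.95% in replicate 1 and 1.94% in replicate 2, against 66.3% ± 2.8 for the embryonic Hbb-y and 30.7% ± 4.3 for the embryonic Hbb-bh1. The median polyadenylated histone variant stood 111 ± 16.6 times above the median replication-dependent histone gene, while the summed TPM of the variants was 1.37 and 1.20 times that of the replication-dependent genes, 81.6% of which was held by Hist1h2ap.

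Genes that decline with age in the early embryo were examined further, after Lin28a, Lin28b and Hmga2 of the progenitor list, 3 such genes, had been seen higher in replicate 2 (14.2 against 24.8, 21.8 against 32.6 and 24.4 against 37.7 TPM). Of 10 others 9 were expressed at a mean of 1 TPM or more, and all 9 were higher in replicate 2: Trim71, a target of let-7 microRNAs, 1.67-fold (3.65 against 5.76 TPM), Sall4 1.49-fold (45.5 against 63.0 TPM), Hmga1 1.42-fold (542.1 against 723.3 TPM), Mycn 1.26-fold, Dnmt3b 1.25-fold and Igf2bp2 1.24-fold, with Igf2bp1 and Igf2bp3 at 1.16-fold and Arid3b at 1.07-fold. With TPM as deposited, Arid3b alone turned, at 34.7 against 34.2 TPM. No one of them was called at 2-fold. Of 17 general progenitor genes, the progenitor list without those 3, 13 were higher in replicate 1, among them Sox9 (1.64-fold), Fabp7 (1.48-fold), Sox2 (1.07-fold) and Vim (1.04-fold), and 4 in replicate 2, among them Hes1 (1.46-fold), Hes3 (1.22-fold) and Pax6 (1.08-fold).

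The neuronal lists were higher in replicate 1, and 4 explanations were weighed as hypotheses. A bias of GC content and length was tested by removing both from the ratios of all genes, after which the newborn neuron list kept a median of 0.50, above every random list, which argues against it as the whole cause. Sensory ganglia taken with the midbrain would raise cranial ganglion genes in replicate 1, yet their median was -0.16. More neurons over an otherwise unchanged progenitor pool would leave early genes and general progenitor genes level with each other. Early genes lay 0.38 lower (-0.38, 95% interval -0.65 to -0.28 in a bootstrap that treats genes as independent). Against all 20 progenitor genes, an alternative chosen after the data were seen, the difference was -0.38 (-0.62 to -0.22). Cell cycle genes (-0.24) and ribosomal protein genes (-0.30) were also lower in replicate 1, so a fall was not particular to early genes. Both lay below the central 95% of matched random lists, -0.17 to -0.04 and -0.19 to -0.11, although these ranges were themselves below 0. The comparison therefore argues only against a pool whose genes all fall alike. It cannot tell a larger share of neurons from a later stage. A more advanced mean stage of the replicate 1 pool would lower early genes there, and their median was -0.32, below every matched random list. It stays open as a candidate explanation, but stage labels are the same for both. Dissection, not tested, may differ. Eye and surface ectoderm genes were 1.93-fold and 1.30-fold higher in replicate 2, and macrophage genes 1.39-fold higher in replicate 1. Atoh1 (5.66-fold) and Ttr (7.72-fold) were also higher in replicate 2, and Hoxa2 was at 0.24 and 1.67 TPM. The hindbrain list, with a median of -0.25, lay inside the random range, with 4 of 6 members higher in replicate 2 and 2 in replicate 1.

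En2 and Pax2 were listed below 1 TPM although both are genes of this region. For reads assigned to an overlapping gene, the test set in advance asked for such a gene at 1 TPM or more. The highest of 3 genes overlapping Pax2 was at 0.32 TPM, and none overlapped En2. Since Pax2 itself had a mean of 0.715 TPM, reads at a level of 0.32 TPM could matter, and the test cannot exclude this for Pax2. A loss of GC-rich transcripts cannot be told apart from low expression: across 83 members of the midbrain, isthmic, forebrain, roof plate and progenitor lists TPM fell with GC content at a Spearman rho of -0.26, short of the -0.3 set in advance and against -0.05 across all protein-coding genes at a mean of 1 TPM or more, and of the top 10% by GC content also set in advance for both, Pax2 lay inside at the 94.6th percentile of protein-coding genes and En2 outside at the 82.0th, with En1 at the 88.5th. No biological explanation was tested.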
